A study of Mus musculus with 12 samples.

How the data were processed

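Bulk tumour RNA was measured in 12 libraries from subcutaneous B16 melanomas grown in C57BL/6 mice. Each tumour carried either a vector for over-expression of Aoah, the gene of acyloxyacyl hydrolase, or the empty Vector. Per the labels, polyA RNA was selected with oligo(dT) beads, ERCC spike-in RNA was added, and libraries were made with the NEBNext Ultra II kit and read as pairs on a NovaSeq instrument. Groups were taken from the sample titles. They were 4 Aoah and 4 Vector tumours of the B16mhgp100 model and 2 Aoah and 2 Vector tumours of the B16F10 model. The labels number the tumours within each model, and do not say that equal replicate numbers mark pairs, so the fits have no pairing term. Nothing says whether tumours came from separate mice, so p-values measure the spread between these tumours.

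The authors deposited expression as log2 values that gave TPM, transcript abundance scaled for gene length and library total, after removal of a pseudocount of 1. The back-transformed TPM summed to between 992185 and 996590 per library. They lay on a grid of 0.01 TPM, within 1e-05, for all but 41 of 32416 gene symbols. Per the submitters' processing notes, RSEM was used and the genome build was mm39. Versions, the annotation release and read trimming are not given in the sources used here. TPM keeps no depth, so reads per library are unknown, and no counting interval is given for any gene. RSEM shares reads between near-identical genes, so values of paralogues, such as the haemoglobin and class II genes, are less certain. The library kit is not stated to keep strand, so antisense partners cannot be told apart.

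The authors also deposited a differential expression table for each model, with the mean normalised count, the log2 fold change and its standard error, a test score and p-values with adjusted p-values. Per the submitters' processing notes, these came from DESeq2. In the authors' deposited table, the mean normalised counts summed to 13867900 for B16mhgp100 and to 14279600 for B16F10. The sign of these fold changes matched Aoah minus Vector in the TPM values. Gene identifiers in these tables were paired with symbols through the gene name table given with the reference, which named 29916 of 31267 identifiers for B16mhgp100 and 25784 of 26878 for B16F10. A further deposited table holds 20 immune receptor repertoire measures per library, as clonotypes, clones, entropy, clonality and isotype ratios. Per the file headers it is a repertoire summary, and its caller settings are not given in the sources used here.

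TPM values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend. Tests were 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 for the adjusted p. Genes were kept with at least 1 TPM in at least as many libraries as the smaller group held. Each model was fitted with its own libraries alone. The difference between the models was tested as an interaction in a fit of all 12 libraries with 4 group means. The fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The plan allowed for a count model if counts per library were found. None were used here, so that model was not run.

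Lists of genes were fixed before the data were examined, 25 lists with 343 members, of which 1 was absent from the table. They cover immune cell types, antigen presentation, interferon responses, melanocyte genes, the cell cycle, stroma, skin, muscle, fat, blood, eicosanoid metabolism, inflammatory signalling, hypoxia and mitochondrial genes. Lists with at least 5 kept members were tested with limma's camera at a preset inter-gene correlation of 0.01, which ranks a list against all other genes. The test was repeated with a correlation estimated per list, and with fry, which tests whether a list's genes move one way on balance. The list test of the difference between the models was chosen after seeing the data. A list score is the mean log2(TPM + 1) of its members in a library.

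Genes named in the text follow a rule fixed before the data were examined. Aoah comes first. Next come genes past the threshold with a mean of at least 1 TPM in a group, the 10 with the largest change in each direction for B16mhgp100 and 5 for B16F10 and for the difference. If none passed, the 3 with the smallest p stand in. Predicted gene models and single receptor segments are left out of these and counted. In each list up to 4 members with the smallest p are named. Genes named outside the rule are said to be so.

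Repertoire measures were compared in B16mhgp100 with an exact 2-sided permutation test of the difference of means, adjusted over the 10 measures that had a value in every library of the model and were no isotype ratio. In B16F10 a test of 2 against 2 libraries cannot go below p = 0.333 by exact permutation, so values are described. The plan named every numeric measure. Isotype ratios were left out, since they stood at 1 in the 4 libraries with no heavy chain clones, and so were measures missing in a library. The Aoah effects of the models were correlated across genes, and set against all 420 arrangements of the labels.

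Alternatives fixed before the data were examined covered the pseudocount, the filter, the scaling, robust and weighted fits, a replicate block, the number of libraries in the fit and leaving out each library. Others, chosen after seeing the data, removed a trend on transcript length with a lowess span of 0.3, crossed the replicate pairs, and left out the library labelled Aoah 4 in the test with an estimated correlation. Transcript lengths came from GENCODE release M21, which is on another build than the authors' and was used for lengths alone. Of the 10429 genes with a mean of at least 5 TPM, 97.1% had a length. No coordinates are given, because no annotation of the authors' build was used here.

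The gene test was checked on simulated values with the spread of the data, in which 100 genes were changed by each of 2 sizes. In B16mhgp100, over 14228 genes, it recovered 19% of genes changed by 1 log2 unit and 69% of those changed by 2. In B16F10, over 14533 genes, it recovered 0% of both, whereas 50 genes passed in the real values. The simulation took each gene's residual SD as its true spread, which 2 against 2 libraries estimate poorly. The 0% is therefore no measure of what the test can find in the real B16F10 values. For the difference, over 16556 genes, the gene test recovered 1% and 18%. With low simulated noise it recovered 100% in each comparison. Genes in the simulated list tests were drawn independently of each other, so these tests say nothing about false calls in lists of correlated genes. In the real B16F10 values the correlation estimated for the MHC class I list was 0.98. In the simulated B16F10 list test, the preset correlation recovered a list moved by 1 log2 unit and called 0 of the 19 others. The estimated correlation missed that list, with an adjusted p of 0.202, and fry recovered it, with 0.0173. In the simulated B16mhgp100 list test the estimated correlation and fry both recovered it, with 0.0013 and 3.43e-05. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.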

Results

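The data hold the transcriptomes of 12 tumours formed by B16 cells, a mouse melanoma line, under the skin of C57BL/6 mice. Some tumours over-expressed Aoah, which encodes acyloxyacyl hydrolase, a lipase known for removing acyl chains from bacterial lipopolysaccharide, and some carried the empty Vector. The B16mhgp100 model had 4 Aoah and 4 Vector tumours, and all of its mice received anti-PD1, an antibody against the T cell checkpoint receptor PD-1, with the first dose on day 10. The B16F10 model had 2 Aoah and 2 Vector tumours, treated from day 6 with anti-PD1 and anti-CTLA4, an antibody against a further checkpoint receptor. Doses were 200 µg of each antibody, given 2 times a week for 4 doses, and tumours were taken 1 day after the last. There was no untreated arm, and model, antibodies and first day change together, so their effects cannot be separated. Between 13775 and 14791 genes reached 1 TPM in a library. The deposited values keep no read depth per library.

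Aoah (ENSMUSG00000021322) was measured first, to check the labels. In B16F10 it stood at 22.7 ± 1.40 TPM in Aoah tumours and 1.12 ± 0.523 TPM in Vector tumours (SD, n = 2 each). The log2 difference was 3.51 (SE 0.29, limma adjusted p = 0.0286), and an exact permutation test of 2 against 2 cannot go below p = 0.333. In B16mhgp100 it stood at 14.6 ± 7.91 TPM in Aoah and 3.12 ± 3.04 TPM in Vector tumours (SD, n = 4 each). The log2 difference of 1.96 (SE 0.59) did not pass, with an adjusted p of 0.694 in limma and p = 0.0571 in an exact 2-sided permutation test over 70 arrangements, of which the smallest possible is 0.0286. The Aoah values of the libraries labelled Aoah 1 to Aoah 4 were 17.92, 22.46, 13.96 and 3.91 TPM. Those of Vector 1 to Vector 4 were 7.58, 0.89, 2.43 and 1.57 TPM. The library labelled Aoah 4 thus lay within the range of the Vector tumours, and its label is unchecked by this gene. Every direction in B16mhgp100 rests in part on it.

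**Figure D1:**
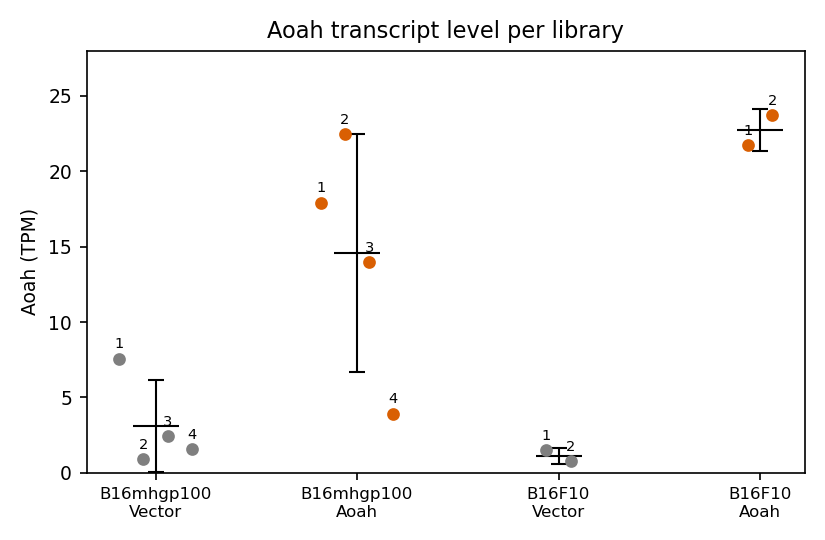
Aoah transcript level in TPM (vertical axis, linear from 0) in each library, by group; points are libraries with their replicate numbers, and bars show the mean and SD. The B16F10 Aoah tumours sit at 21.75 and 23.73 TPM, and the B16mhgp100 library labelled Aoah 4 sits at 3.91 TPM, below the highest Vector tumour at 7.58 TPM.

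The same library stood apart in many genes of other tissues. Its keratinocyte score was 6.66 against at most 2.04 in the 11 other libraries, and its skeletal muscle score was 8.05 against at most 5.89. Krt14, a keratin of the basal epidermis, stood at 600.09 TPM there and at no more than 6.23 TPM elsewhere. Mylpf, a fast muscle myosin light chain, stood at 642.73 TPM. Sox10, a transcription factor of the melanocyte lineage, stood at 93.56 TPM there and between 518.84 and 903.94 TPM in the others. Not all melanocyte genes were low there. Mlana stood at 1663 TPM, within the range of 1186.56 to 1896.92 TPM of the others. Its correlations with the others across genes ran from 0.892 to 0.907, and the lowest correlation among the other 11 was 0.952. Ribosomal protein genes made up 22.2% of its TPM. Its deviation from the other libraries also declined with transcript length, with a Spearman rho of -0.458 across genes, which are not independent replicates.

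The first comparison asks which genes differ between Aoah and Vector tumours in B16mhgp100 under anti-PD1. No single gene passed. As lists, antigen presentation, cytotoxic and myeloid genes ranked higher in Aoah tumours with the preset correlation in limma's camera, and 0 of the 21 lists passed with an estimated correlation. The genes for MHC class II presentation, which display peptides to CD4 T cells, had all 7 kept members above 0, with a mean log2 fold change of 0.59. Cd74, the class II invariant chain, stood at 629 ± 165 TPM in Aoah and 410 ± 198 TPM in Vector tumours (SD, n = 4 each), and H2-DMa, a peptide loading chain, had a log2 fold change of 0.68. CD8 and cytotoxic effector genes had all 8 members above 0 with a mean of 0.49, and Gzmb and Prf1, which encode granzyme B and perforin, had log2 fold changes of 0.99 and 0.72. With the preset correlation both lists passed (adjusted p = 1.96e-06 and 2.57e-06), and neither did with an estimated correlation (adjusted p = 0.497 and 0.415). Without Vector 2 the class II mean was 0.31, and the list still passed.

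Myeloid and inflammatory lists also ranked higher with the preset correlation, some of them through single libraries. Of the macrophage and monocyte genes, 17 of 18 were above 0 with a mean of 0.50 (adjusted p = 4.36e-05, and 0.516 with an estimated correlation). C1qa, a complement chain made by macrophages, stood at 439 ± 332 TPM in Aoah and 165 ± 117 TPM in Vector tumours (SD, n = 4 each), and Ccr2 had a log2 fold change of 0.69. Without Aoah 2 the macrophage mean was 0.03 and the call was lost (adjusted p = 0.10). The mean was 0.13 without Vector 2, 0.84 without Vector 1 and 1.02 without Aoah 3, and the list passed each time. Of the toll-like receptor and inflammatory cytokine genes, 13 of 15 were above 0 with a mean of 0.50 (adjusted p = 8.14e-08, and 0.497 with an estimated correlation). The chemokine genes Ccl4 and Ccl2 had log2 fold changes of 1.20 and 1.11. All 5 neutrophil genes lay above 0, with a mean of 0.55 and Il1r2 at 1.00 (adjusted p = 0.00663, and 0.513 with an estimated correlation). This call was lost without Aoah 4, at 0.21 with 3 of 5 genes above 0 (adjusted p = 0.311), without Aoah 2, at 0.26, and without Vector 2, at 0.31, and the mean was 1.03 without Aoah 3. Dendritic cell genes had a mean of 0.31, with Irf8 at 0.60 and Naaa at 0.76 (adjusted p = 0.0128, and 0.513 with an estimated correlation). Their call was lost without Aoah 4, at 0.36 (adjusted p = 0.0544), without Aoah 2, at 0.12, and without Vector 2, at 0.11. The mean was 0.50 without Aoah 3 and 0.53 without Vector 1.

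For T cell genes the mean was 0.11, with Lat at 0.55 and Cd247, a T cell receptor signalling chain, at -0.71 (adjusted p = 0.0249, and 0.513 with an estimated correlation). The T cell call was lost without Aoah 4, at 0.03 (adjusted p = 0.473), without Aoah 3, at 0.10, and without Vector 2, at -0.03. The mean was 0.22 without Vector 1 and 0.07 without Vector 4. Lat was at 0.28 without Aoah 4, where it stood at 6.8 TPM. Cd247 stood at 0.84 TPM in Aoah 4 and at 2.87, 4.69 and 4.71 TPM in Aoah 1 to Aoah 3. MHC class I genes had a mean of 0.18, with Psmb9 at 0.64 and H2-T23 at 0.56 (adjusted p = 0.00035, and 0.513 with an estimated correlation). That mean was 0.08 without Aoah 1, 0.04 without Vector 2 and 0.27 without Aoah 4, and the list passed each time. Psmb9 stood at 550.8 TPM in Aoah 4 and between 205.48 and 292.75 TPM in the other Aoah libraries. The type I interferon-stimulated list passed as higher at a mean of 0.01 and a median of -0.05, with Zbp1 at 0.69 and Xaf1 at 0.33 (adjusted p = 0.0199, and 0.553 with an estimated correlation). The call was lost without Aoah 1, Aoah 2, Aoah 3, Vector 1 or Vector 2, at means of -0.14, -0.07, -0.02, -0.01 and -0.08. The list passed without Aoah 4, Vector 3 or Vector 4, at 0.28, 0.09 and 0.05. This list, like every list of this model, was ranked against a background in which the median log2 fold change of all genes was -0.20. That median was -0.02 without Aoah 4 and between -0.19 and -0.27 without any other single library. Median-of-ratios scaling moves the median by 0.205. Hypoxia and glycolysis genes had a mean of 0.30, with Hk2, a hexokinase, at 0.57 and Ankrd37 at 0.94 (adjusted p = 1.38e-05, and 0.513 with an estimated correlation). Their mean was 0.14 without Aoah 2, 0.18 without Aoah 3 or Vector 3 and 0.65 without Aoah 4, and the list passed each time.

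Fibroblast and collagen genes had a mean of 0.40, with Dcn at 2.10 and Thy1 at 0.87 (adjusted p = 0.00517, and 0.553 with an estimated correlation). The call was lost without Aoah 2, at -0.03, without Vector 2, at 0.07, and without Aoah 4, at 0.43 (adjusted p = 0.0705), and the mean was 0.90 without Aoah 3 and 0.74 without Vector 1. Red blood cell genes had a mean of 0.48, with Hba-a1 at 0.70 and Hba-a2 at 0.56 (adjusted p = 0.0168, and 0.516 with an estimated correlation). Their mean turned to -0.23 without Aoah 4 and was 0.28 without Vector 3, with the call lost both times, and was 0.81 without Aoah 1 and 0.78 without Aoah 2.

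Melanocyte and cell cycle genes ranked lower with the preset correlation. Of the melanocyte and pigment genes, 14 of 15 lay below 0, with a mean of -0.51, Slc24a5 at -0.67 and Trpm1 at -0.63 (adjusted p = 0.0243, and 0.557 with an estimated correlation). Without Aoah 4 the mean was -0.11 and the list no longer passed (adjusted p = 0.104), nor did it without Aoah 2, at -0.57, or Vector 2, at -0.41. Of the cell cycle genes, 19 of 20 lay below 0, with a mean of -0.38 (adjusted p = 0.00663, and 0.553 with an estimated correlation). Without Aoah 4, whose cell cycle score of 5.83 lay below the others, the mean was -0.12 and the list still passed (adjusted p = 0.00143). Mki67, the gene of the proliferation marker Ki-67, stood at 23.1 ± 9.31 TPM in Aoah and 45.9 ± 5.28 TPM in Vector tumours (SD, n = 4 each), a log2 fold change of -1.07, or -0.71 without Aoah 4, and Cenpf was at -0.38.

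The remaining lists did not pass in this model, although several did with a single library left out. Mean log2 fold changes were 0.14 for CD4 and regulatory T cell genes, with Ikzf2 at 0.49 and Tnfrsf18 at 0.20, 0.25 for skeletal muscle, -0.20 for endothelium, with Cdh5 at -0.80, and -0.32 for mitochondrially encoded genes. Median-of-ratios scaling turned the endothelium mean to 0.02. Cdh5 stood at 5.62 TPM in Aoah 4 and between 15.59 and 25.24 TPM in the other Aoah libraries. The CD4 mean was 0.01 without Aoah 4. Ikzf2 stood at 4.86 TPM in that library (at most 1.4 in the other Aoah libraries) and Tnfrsf18 at 7.66 TPM (at most 4.44). The checkpoint and interferon-gamma lists had medians of -0.06 and -0.07, with Lag3 at 0.57, Havcr2 at -0.49, Socs1 at 0.73 and Cxcl11 at -0.42. The eicosanoid and phospholipid list had a mean of 0.20 and a median of -0.13, with Ptgs2 at 0.86 and Ptgis at 1.49. The skeletal muscle list passed as lower without Aoah 4, at -1.25 (adjusted p = 0.0246), and as higher without Aoah 1, Aoah 3 or Vector 1, at 1.16, 0.90 and 1.10. The interferon-gamma list passed as higher without Aoah 4, at 0.28 with 13 of 16 above 0 (adjusted p = 0.00147), and without Vector 3 or Vector 4, at 0.13 and 0.10. The checkpoint list passed as higher without Vector 1 or Vector 4, at 0.21 and 0.08. The CD4 list did so without Vector 1 or Vector 3, at 0.27 and 0.18, and the eicosanoid list without Aoah 3, at 0.41. The endothelium list passed as lower without Vector 2, at -0.38. The endothelium mean was -0.07 without Vector 1 and -0.12 without Aoah 3, and the mitochondrial mean was -0.17 without Aoah 4. Without Vector 2 the skeletal muscle and CD4 means turned to -0.17 and -0.07, and without Aoah 2 the eicosanoid mean turned to -0.03.

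Lists with fewer than 5 kept members were not tested. NK cell genes had a mean of 0.41, with Klrd1 at 0.83, B and plasma cell genes had 1.64, with Igkc at 1.89, keratinocyte genes had 1.04, with Krt14 at 1.59, and adipocyte genes had Lpl at 0.71. Without Aoah 4 the keratinocyte mean was -0.67, with 0 of 2 genes above 0 and Krt14 at -0.56, and the adipocyte mean was -0.93, with Lpl at 0.08. The NK cell and B and plasma cell means were then 0.17 and 1.13.

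By single genes, 0 of 14228 passed in limma, and 350 had an unadjusted p below 0.05, 158 higher and 192 lower, where chance gives 711.4. The number at an unadjusted p below 0.05 was 1184 without Aoah 4, 654 without Aoah 3, 187 without Vector 3 and 180 without Vector 4, so it depends on single libraries. With array weights it was 2186. No list had a member past the threshold adjusted over the list alone. The smallest p values among higher genes belonged to Stc1, the gene of the secreted hormone stanniocalcin, at a log2 fold change of 1.11 (SE 0.20, adjusted p = 0.694), to Pagr1a at 2.92 and to Spaca9 at 1.03. Those among lower genes belonged to n-R5s185, a 5S ribosomal RNA gene listed at 0 in every Aoah library (adjusted p = 0.0524), to Dkc1, a gene of snoRNA-guided RNA modification, at -0.80 and to Ahsg at -1.05. The Aoah and Vector values did not overlap for 837 genes, 5.88% of those tested, where chance gives 2.86%. In the authors' deposited table, there were 3 genes past the threshold, all higher in Aoah tumours. They were Retnla, with a log2 fold change of 6.30 and an adjusted p of 0.0455 in the authors' deposited table, Stc1, with 1.59 and the same adjusted p, and an identifier without a symbol. Across 13558 genes the fold changes computed here correlated with those of the authors' deposited table at r = 0.909.

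Of the 21 lists tested, 14 passed with the preset correlation, 12 higher and 2 lower, and 0 did with an estimated correlation or with fry. Without the library labelled Aoah 4, 10 passed with the preset correlation, 8 higher and 2 lower, among them hypoxia and glycolysis with all 15 genes above 0 and a mean of 0.65, and again 0 with an estimated correlation. Without Aoah 2 the number with the preset correlation was 9, and without Vector 2 it was 10.

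The second comparison asks the same in B16F10 under anti-PD1 and anti-CTLA4. With the preset correlation, lists of T cell, cytotoxic, checkpoint, antigen presentation and interferon response genes ranked higher in Aoah tumours, and those of collagen and endothelium ranked lower. With an estimated correlation none of these lists passed (adjusted p from 0.354 to 0.384). With 2 against 2 libraries that test also missed a simulated list moved by 1 log2 unit (adjusted p = 0.202). A list that did not pass it is therefore not shown to be unchanged. The melanocyte list also lost its call, at an estimated correlation of -0.0392, below the preset 0.01. A lost call in B16F10 thus does not show that correlated members were the reason. Vector 2, 1 of the 2 controls, stood apart, with 10.4% of its TPM from mitochondrially encoded genes (at most 6.38% in the other libraries of both models). Its deviation declined with transcript length at a Spearman rho of -0.315, and its median correlation with the others, 0.959, was the lowest after that of Aoah 4 of B16mhgp100. Without Vector 2 the lists that ranked higher still passed with the preset correlation, and the endothelium list did not. Of 14533 genes, 50 passed in limma, 42 higher and 8 lower. These calls rest on 4 libraries. Leaving out 1 of them keeps a lone library in a group, so such fits cannot judge the calls. H2-DMb1, a class II peptide loading chain, rose from 27.1 ± 1.07 to 247 ± 24.5 TPM (SD, n = 2 each), a log2 fold change of 3.14 (SE 0.17, adjusted p = 0.0178). Retnla, a secreted protein of alternatively activated macrophages, fell from 455 ± 163 to 17.2 ± 2.40 TPM (SD, n = 2 each), a log2 fold change of -4.61 (SE 0.28, adjusted p = 0.0238).

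MHC class II presentation had all 9 members above 0 and a mean log2 fold change of 2.12, and 6 of them passed. H2-Ab1, Cd74 and H2-DMa rose by 2.53, 2.47 and 2.61. Cd74 stood at 1424 ± 132 TPM in Aoah and 258 ± 47.8 TPM in Vector tumours (SD, n = 2 each). MHC class I presentation, which displays peptides to CD8 T cells, had all 13 members above 0 and a mean of 2.04, and 3 passed. They were Psmb8, an immunoproteasome subunit, at 3.18, H2-K1 at 2.35 and Tap2, a peptide transporter, at 2.25. Tap1 had a log2 fold change of 2.70 (adjusted p = 0.0571). Both lists passed with the preset correlation (adjusted p = 2.76e-12 and 7.71e-14) and had an adjusted p of 0.354 with an estimated correlation. Adjusted over the list alone, 9 of 9 and 13 of 13 members passed.

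T cell genes had all 16 members above 0 with a mean of 1.91. None of them passed over all genes, and 16 passed adjusted over the list alone. Zap70 and Cd3d, which encode a kinase and a chain of the T cell receptor complex, had log2 fold changes of 2.25 and 2.12, and Cd6 and Ubash3a had 2.29 and 2.02. CD8 and cytotoxic effector genes had all 11 members above 0 with a mean of 2.12, and 3 passed, or 10 adjusted over the list alone. Cd8a rose from 0.50 ± 0.198 to 13.2 ± 1.02 TPM (SD, n = 2 each), a log2 fold change of 3.25, and Cd8b1 and the chemokine gene Ccl5 rose by 2.76 and 2.96. Nkg7, a granule protein of cytotoxic cells, had 3.94 (adjusted p = 0.0546). Among checkpoint and exhaustion genes, 8 of 9 lay above 0 with a mean of 1.72, and 1 passed, or 7 adjusted over the list alone. That gene was Pdcd1, which encodes PD-1, at 3.05, and Tigit, Lag3 and Cxcr6 had 2.88, 2.79 and 2.48. The 3 lists passed with the preset correlation (adjusted p = 2.37e-13, 1.39e-11 and 4.71e-07), with an adjusted p of 0.354 for each with an estimated correlation. The 5 CD4 and regulatory T cell genes had a mean of 1.36, with Il2rb at 2.80, Tnfrsf18 at 1.37, Cd4 at 1.25 and Tnfrsf4 at 1.17, and 3 passed adjusted over the list alone (adjusted p = 0.00148, and 0.384 with an estimated correlation). Without Vector 2 that mean was 0.84, and the list passed.

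Among interferon-gamma response and chemokine genes 14 of 15 lay above 0 with a mean of 1.83. None passed over all genes and 13 did adjusted over the list alone, with Gbp5 at 2.36, Socs1 at 2.12, the class II transactivator gene Ciita at 1.98 and Cd274, which encodes PD-L1, at 1.72 (adjusted p of the list 9.67e-10, and 0.383 with an estimated correlation). Of the type I interferon-stimulated genes, 16 of 17 lay above 0 with a mean of 1.11. Bst2, a membrane protein that retains viruses, passed at 1.44, 11 genes passed adjusted over the list alone, and Zbp1, Oasl2 and Irf7 had 2.81, 2.07 and 1.74 (adjusted p of the list 9.81e-08, and 0.384 with an estimated correlation). Without Vector 2 the mean was 0.68, and the list passed. Toll-like receptor and inflammatory cytokine genes had a mean of 0.83, with Ccl4 at 2.23, Ccl3 at 1.55, Tnf at 1.38 and Tlr2 at 1.35, and 5 of 14 passed adjusted over the list alone (adjusted p = 2.19e-05, and 0.354 with an estimated correlation). Macrophage and monocyte genes had a mean of 0.36, with Ly6c2 at 2.17, Fcgr1 at 1.18, C1qa at 1.14 and C1qc at 1.03 (adjusted p = 0.00702, and 0.483 with an estimated correlation). Adjusted over the list alone, 6 macrophage genes passed as higher and 1 as lower. The list passed without Vector 2, at 0.17, and without Vector 1, at 0.56. Melanocyte genes had a mean of 0.21, with Trpm1 at 1.00, Pmel at 0.98, Sox10 at 0.57 and Ednrb at -1.94 (adjusted p = 0.0254, and 0.354 with an estimated correlation). Of these, 4 passed as higher and 1 as lower adjusted over the list alone. The melanocyte call was lost without Aoah 1, at 0.21 (adjusted p = 0.0557), and without Vector 1, at 0.15 (adjusted p = 0.263).

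Of the fibroblast and collagen genes 11 of 12 lay below 0, with a mean of -1.0, and 7 passed adjusted over the list alone (adjusted p of the list 5.72e-06, and 0.354 with an estimated correlation). Postn had a log2 fold change of -2.67, Col6a1 of -1.54, Col1a2 of -1.38 and Col1a1 of -1.30. Col1a1 stood at 42.5 ± 14.8 TPM in Aoah and 103 ± 2.98 TPM in Vector tumours (SD, n = 2 each). Endothelial genes had a mean of -0.71, with Pecam1 at -1.57, Kdr and Flt1, which encode receptors for vascular endothelial growth factor, at -1.21 and -1.12, and Eng at 0.81 (adjusted p = 0.00043, and 0.354 with an estimated correlation). Adjusted over the list alone, 7 of the 12 passed as lower and 1 as higher. Without Vector 2 the endothelial mean was -0.58 and the call was lost (adjusted p = 0.0702). Cell cycle genes had a mean of -0.42, with Mki67 at -2.18, Cenpf at -1.29, Ccnb1 at -0.62 and Mcm3 at -0.56 (adjusted p = 0.00328, and 0.564 with an estimated correlation), and 0 of the 20 passed adjusted over the list alone. Their scores were 6.21 and 6.30 in Aoah and 7.08 and 6.28 in Vector tumours. Without Vector 1 the mean was -0.02 and the call was lost (adjusted p = 0.712), so it rests on that library, and without Vector 2 the mean was -0.82. Mitochondrially encoded genes had a mean of -0.42, with mt-Nd2 at -0.95, mt-Atp8 at -0.78, mt-Nd5 at -0.77 and mt-Nd4l at -0.77 (adjusted p = 0.00568, and 0.557 with an estimated correlation). Without Vector 2 their mean turned to 0.10 and without Aoah 2 it was -0.34, with the call lost both times, and without Vector 1 it was -0.95.

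The other lists did not pass in B16F10. Dendritic cell genes had a mean of 0.40, with Irf8 at 3.04, Wdfy4 at 1.5, Fscn1 at -0.90 and Clec10a at -1.02. None passed over all genes, and adjusted over the list alone 2 passed as higher and 2 as lower. Hypoxia and glycolysis genes had a mean of 0.29, with Hk2 at 0.99, Pfkp at 0.92, Aldoa at 0.73 and Ndrg1 at 0.43. The eicosanoid and phospholipid list had a mean of -0.23, with Ltc4s, the leukotriene C4 synthase gene, at -1.58, Cd36 at -1.52, Enpp2 at -0.97 and Ptges2 at 0.81. Skeletal muscle and red blood cell genes had means of -0.94 and -0.75, with Mylpf at -2.02, Acta1 at -1.67, Hbb-bt at -1.11 and Hbb-bs at -1.05. With 1 library left out the muscle list passed each time, as lower without Aoah 1, Aoah 2 or Vector 1, at -0.93, -1.08 and -2.65, and as higher without Vector 2, at 0.92. The red blood cell list passed as lower without Aoah 1 or Vector 1, at -0.89 and -1.52, and its mean turned to 0.03 without Vector 2. The hypoxia list passed as higher without Vector 1, at 0.55, and its mean was 0.04 without Vector 2. The dendritic mean was 0.23 without Vector 2, and the eicosanoid mean was -0.38 without Vector 2 and -0.15 without Vector 1. Lists with fewer than 5 kept members were not tested. NK cell genes had a mean of 1.22, with Klrd1 at 1.56, Klrk1 at 1.27 and Xcl1 at 0.82, and 3 of 3 passed adjusted over the list alone. B and plasma cell genes had a mean of -1.09, with Igkc at -1.56 and Ighm at -0.61, and both falls rest on Vector 1. Igkc stood at 29.15 TPM in Vector 1, 0 TPM in Vector 2 and 1.67 and 0.29 TPM in Aoah tumours. Ighm stood at 22.25, 1.89, 4.35 and 4.42 TPM in the same order. Adipocyte genes had a mean of -0.95, with Lpl at -1.46 and Fabp4 at -1.33. Neutrophil genes had a mean of 0.36, with Csf3r at 0.87 and Mmp9 at -0.16. Keratinocyte genes had a mean of 1.30, and Krt10 and Lor, genes of the outer epidermis, passed at 3.11 and 2.57, from 0.430 and 0.135 TPM in Vector tumours, with Sfn at -0.80 and Krt14 at 0.34.

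Outside the lists, Apol9a rose by 3.59 (SE 0.34, adjusted p = 0.0384), and Rbm25, a splicing factor gene, fell by 1.94 (SE 0.20, adjusted p = 0.0433). The small nucleolar RNA genes Snord118, Snord94 and Snord15a also passed as higher, at means of 53.2, 24.0 and 10.4 TPM in Aoah tumours, and are listed at 0 in both Vector libraries, so no fold is given. Such short RNAs are poorly measured in polyA libraries. Of the 50 genes, 11 were predicted gene models or receptor segments and are not named by the rule. The Aoah and Vector values did not overlap for 7346 genes, 50.5%, where chance gives 33.3%.

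The authors' deposited table for B16F10 called 1222 genes, 666 higher and 556 lower, with 35 of the 50 among them in the same direction. Across 13808 genes the fold changes computed here correlated with those of the authors' deposited table at r = 0.930. Of the 20 lists tested, 15 passed with the preset correlation, 11 higher and 4 lower, and 0 with an estimated correlation or with fry, whose smallest adjusted p was 0.0527. In a fit of all 12 libraries, 5 lists passed with an estimated correlation, namely T cells, CD8 and cytotoxic effectors, checkpoint genes, MHC class I and MHC class II (adjusted p = 0.0175, 0.0094, 0.0175, 0.0175 and 0.046), an alternative chosen after seeing the data.

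**Figure D2:**
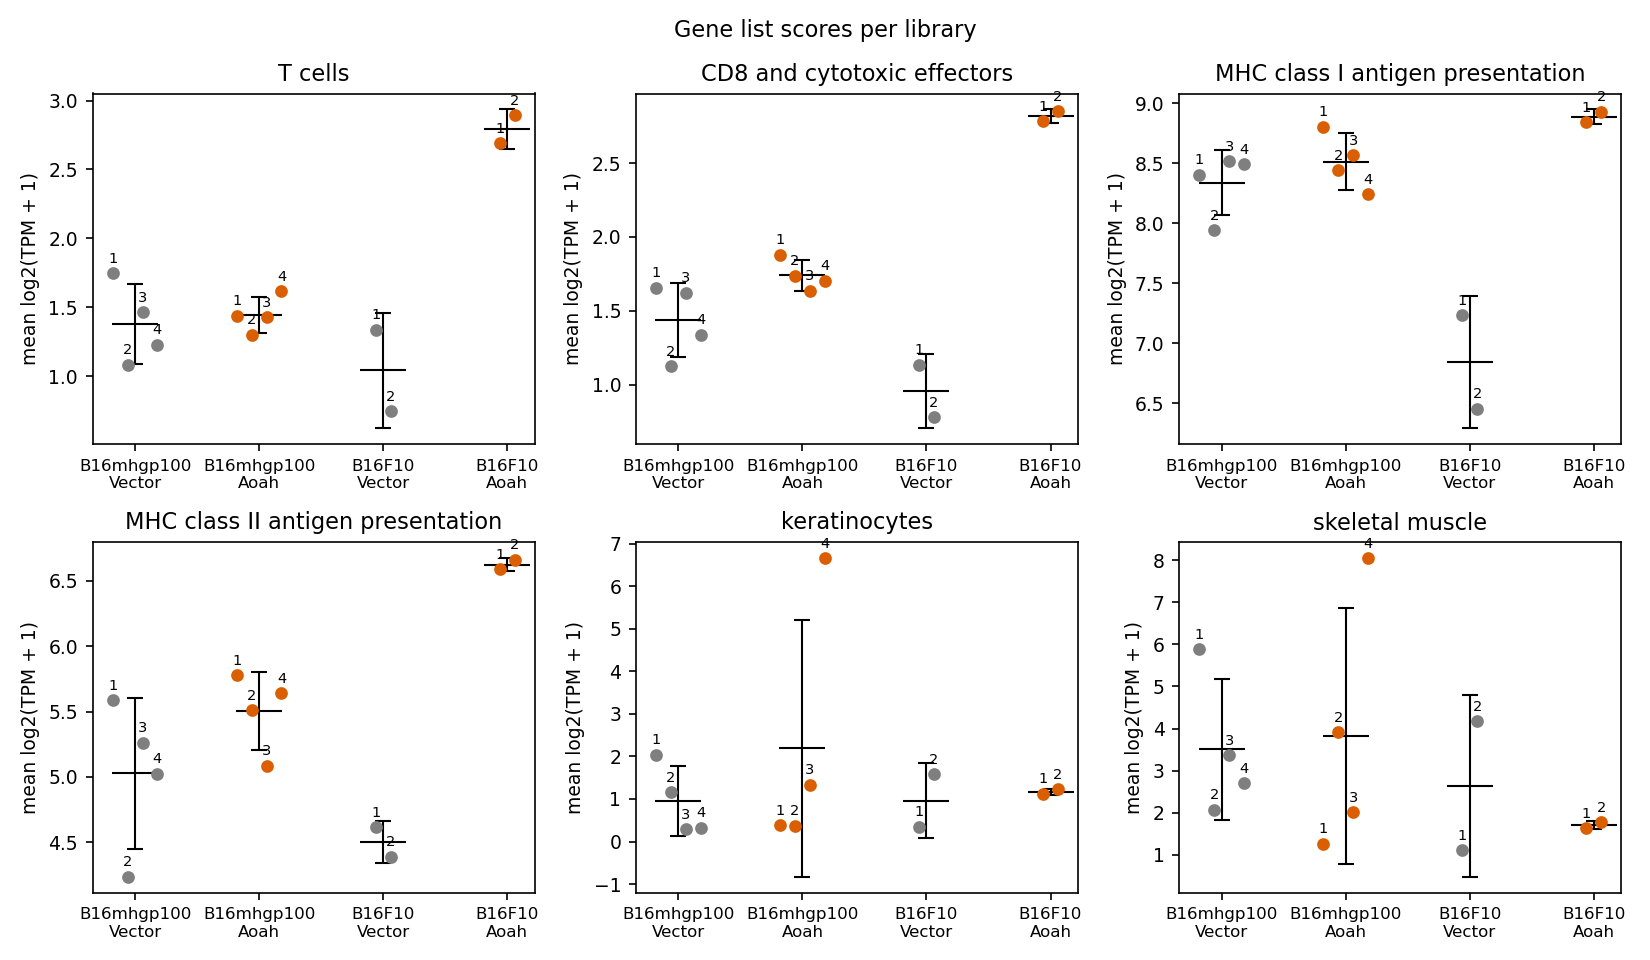
Scores of 6 gene lists per library, as the mean log2(TPM + 1) of the list's members (vertical axes, which do not start at 0), by group; points are libraries with their replicate numbers, and bars show the mean and SD. In B16F10 the T cell scores are 2.69 and 2.89 in Aoah and 1.34 and 0.743 in Vector tumours, and the library labelled Aoah 4 of B16mhgp100 has the highest keratinocyte score, 6.66.

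The third comparison asks whether the Aoah effect differed between the models, as B16mhgp100 minus B16F10. With the preset correlation, the T cell, MHC class I and MHC class II lists that ranked higher in B16F10 Aoah tumours were lower in this difference, and with an estimated correlation MHC class II did not pass (adjusted p = 0.149). Of 16556 genes, 5 passed in limma, 1 higher and 4 lower, and 936 had an unadjusted p below 0.05. Without Aoah 4 these numbers were 45 and 2161, without Aoah 1 of B16F10 they were 11 and 579, and with array weights 31 and 1643. The number past the threshold was 23 without Aoah 2 of B16F10, 16 and 22 without its Vector 1 and Vector 2, 3 without Aoah 2 or Vector 4 of B16mhgp100, and 2 without Vector 1 or Vector 3 of that model. H2-DMb1 differed by -2.82 (SE 0.32, adjusted p = 0.0147), Psmb8 by -2.82 (SE 0.38, adjusted p = 0.0433) and Apol9a by -3.52 (SE 0.44, adjusted p = 0.0302). Apol9a stood at 150 ± 14.2 TPM in B16mhgp100 Vector tumours (SD, n = 4) and at 9.95 ± 4.88 TPM in B16F10 Vector tumours (SD, n = 2). With 1 of the 12 libraries left out, H2-DMb1 no longer passed without Vector 1, Vector 3 or Vector 4 of B16mhgp100. Apol9a no longer passed without Aoah 2 or any Vector library of B16mhgp100 or either Aoah library of B16F10. Psmb8 passed only without Aoah 4 or Vector 2 of B16mhgp100 or a Vector library of B16F10. The other 2 were the gene models Gm12238 at -5.0 and Gm56050 at 5.46, named after their values were seen. The higher genes with the smallest p that the rule names did not pass. They were Rnase2a at 4.88 (adjusted p = 0.0616), Rbm25 at 1.62 and Rps3a1, a ribosomal protein gene, at 1.12. Rescaling without mitochondrial, immunoglobulin and haemoglobin genes and Aoah gave 8 genes, 3 higher and 5 lower. Aoah itself differed by -1.55 (SE 0.93, adjusted p = 0.849).

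Effects on T cell genes were lower in B16mhgp100 for all 16 members, with a mean difference of -1.85, Ubash3a at -2.14 and Zap70 at -1.98. They were lower for all 12 CD8 and cytotoxic effector genes, with a mean of -1.64, Cd8a at -3.07 and Cd8b1 at -2.41, and for all 9 checkpoint genes, with a mean of -1.65, Tigit at -3.22 and Pdcd1 at -2.84. All 13 MHC class I genes were lower too, with a mean of -1.87 and H2-K1 at -2.18. These 4 lists passed with the preset correlation, and each had an adjusted p of 0.0367 with an estimated correlation. Adjusted over the list alone, 13, 8, 6 and 10 members passed. MHC class II differed by a mean of -1.65, with H2-DMa at -1.93, and CD4 and regulatory T cell genes by -1.22, with Il2rb at -2.72 and Ccr8 at -1.48. Both passed with the preset correlation (adjusted p = 4.78e-10 and 5.69e-05), and both had an adjusted p of 0.149 with an estimated correlation. Without Vector 2 of B16F10 the CD4 mean was -0.78, and the list passed. Interferon-gamma and type I interferon genes differed by means of -1.70 and -1.10, with Igtp at -2.97 and Irf7 at -1.44 (adjusted p = 0.246 and 0.268 with an estimated correlation). Without Vector 2 of B16F10 the type I mean was -0.67, and the list passed. Melanocyte genes differed by -0.72, with Trpm1 at -1.63 and Ednrb at 2.68 (adjusted p = 0.618 with an estimated correlation). Their call was lost without Aoah 2 or Vector 2 of B16mhgp100, at -0.78 and -0.62, and without Vector 1 of B16F10, at -0.66. The mean was -0.32 without Aoah 4.

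In the other direction, fibroblast and collagen genes differed by a mean of 1.37, with all 13 above 0, Postn at 2.14 and Fap at 0.98, and endothelial genes by 0.51, with Pecam1 at 1.17 and Eng at -1.20. Both had an adjusted p of 0.349 with an estimated correlation. The endothelial call was lost without Vector 2 of B16F10, at 0.38, and its mean was 0.32 without Vector 2 of B16mhgp100. Skeletal muscle, red blood cell and eicosanoid genes differed by means of 1.24, 1.22 and 0.45, with Mylpf at 3.21, Hbb-bs at 1.47 and Ltc4s at 3.13 (adjusted p = 0.618, 0.534 and 0.534 with an estimated correlation). Without Aoah 4, with its high muscle and haemoglobin transcripts, these calls were lost, at means of -0.17, 0.52 and 0.55. They were also lost without Vector 2 of B16F10, at -0.29, 0.45 and 0.57, and without Aoah 2 of B16F10, at 1.31, 1.08 and 0.45. The muscle call was lost as well without Aoah 1 of B16F10, at 1.17, and without Vector 2 or Vector 4 of B16mhgp100, at 0.76 and 0.97. The eicosanoid call was lost as well without Aoah 1, Aoah 2 or Vector 2 of B16mhgp100, at 0.40, 0.20 and 0.34, and without Aoah 1 or Vector 1 of B16F10, at 0.45 and 0.34. Muscle means were 2.09 without Aoah 1 and 2.04 without Vector 1 of B16mhgp100, and without Vector 1 of B16F10 the muscle and red blood cell means were 2.77 and 2.00.

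In all, 14 lists passed with the preset correlation, 5 higher and 9 lower, 6 passed with fry, and median-of-ratios scaling gave 3 higher and 9 lower. Lists that did not pass had mean differences of 0.95 for B and plasma cells, -0.11 for dendritic cells, 0.14 for macrophages, 0.69 for neutrophils, 0.04 for the cell cycle, 1.09 for keratinocytes, 0.56 for adipocytes, -0.28 for toll-like receptor genes, 0.01 for hypoxia genes and 0.10 for mitochondrial genes. With a single library left out, the lists for B and plasma cells, macrophages, neutrophils, the cell cycle, keratinocytes, adipocytes, hypoxia and mitochondrial genes passed as higher in some fits. Without Aoah 4 the cell cycle and hypoxia lists did so, at 0.30 and 0.36, and the keratinocyte and adipocyte means turned to -0.64 and -0.12. Without Vector 1 and Vector 2 of B16F10 the B and plasma cell mean was 0.20 and 1.78. The mitochondrial mean was then 0.63 and -0.42, and the cell cycle mean -0.36 and 0.44. The macrophage mean was -0.33 without Aoah 2 and 0.66 without Aoah 3 of B16mhgp100, and the dendritic mean turned to 0.09 without its Vector 1. The NK list, at -0.81, was not tested. Since the models differ in antibodies and first day, the difference belongs to the whole setting.

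**Figure D3:**
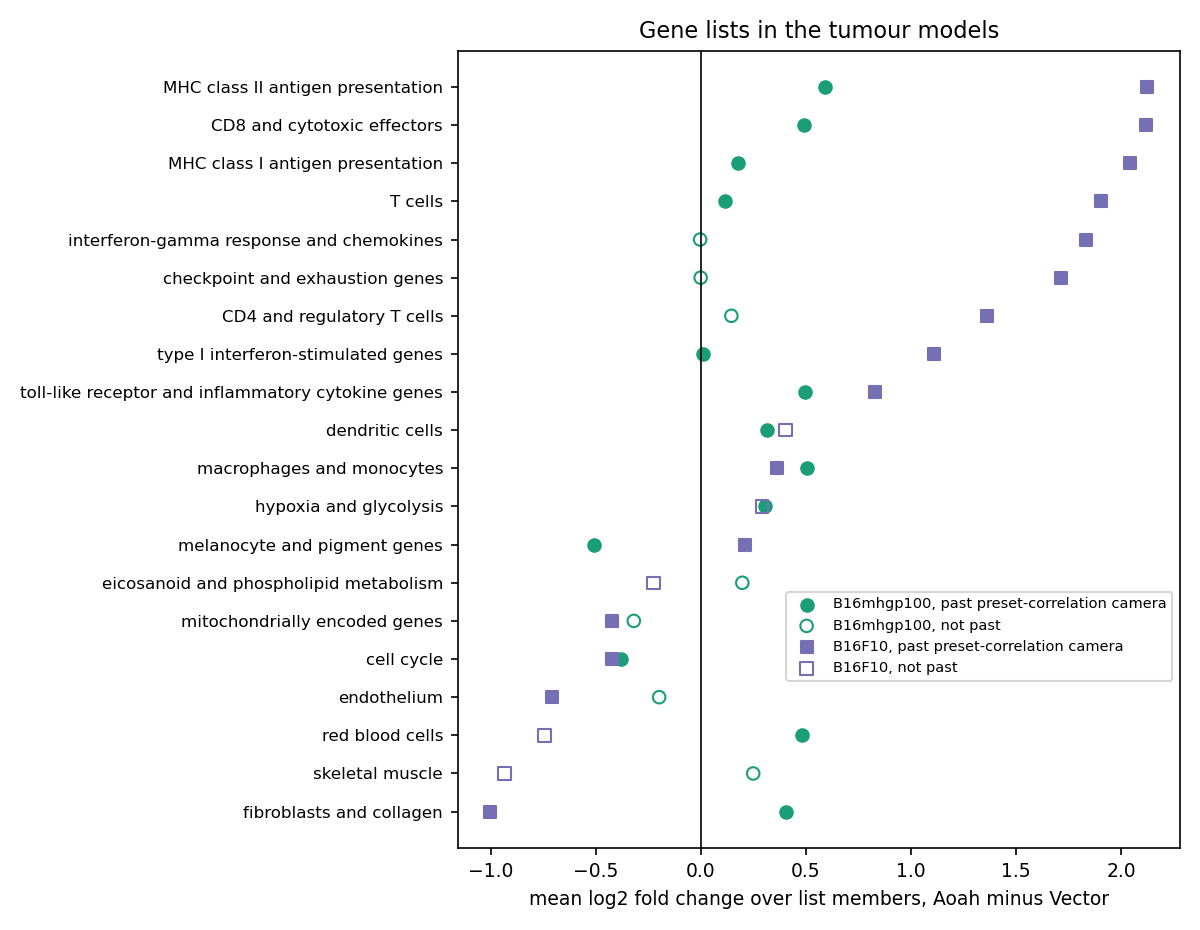
Mean log2 fold change over the members of each list, Aoah minus Vector (horizontal axis), for lists tested in both models; circles are B16mhgp100 and squares B16F10, filled where limma's camera with the preset correlation passed. MHC class II genes lie at 0.59 in B16mhgp100 and 2.12 in B16F10, and fibroblast genes at 0.40 and -1.0. With an estimated correlation 0 of these lists passed in either model. In B16F10 that test also missed a simulated list moved by 1 log2 unit.

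The repertoire table asks whether immune receptor clones differed. In B16F10, T cell receptor beta clones numbered 30 and 32 in Aoah tumours and 2 and 1 in Vector tumours, and alpha clones numbered 22 and 21 against 1 and 2. Beta clonotypes numbered 20 and 21 against 2 and 1, and alpha clonotypes 19 and 17 against 1 and 2. Both Aoah libraries lay above both Vector libraries in these 4 measures, and with 2 against 2 no exact permutation test can pass. Heavy chain clones numbered 2 and 3 in Aoah tumours and 45 and 0 in Vector tumours, and light chain clones 4 and 2 against 72 and 3. In B16mhgp100, beta clones numbered 5.75 ± 1.26 in Aoah and 4.75 ± 2.36 in Vector tumours (SD, n = 4 each), and alpha clones 4.25 ± 3.77 and 3.75 ± 3.86 (SD, n = 4 each). Light chain clones numbered 25.0 ± 21.9 in Aoah and 4.75 ± 6.95 in Vector tumours (SD, n = 4 each). By exact 2-sided permutation 0 of the 10 measures passed or had an unadjusted p below 0.05, and the smallest p was 0.229, for light chain clones (adjusted p = 0.857). No clone number lay below its clonotype number, so clones are read here as totals over clonotypes and not as distinct receptors. They are whole numbers from bulk RNA, low and not scaled for depth, and reads per library are unknown.

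**Figure D4:**
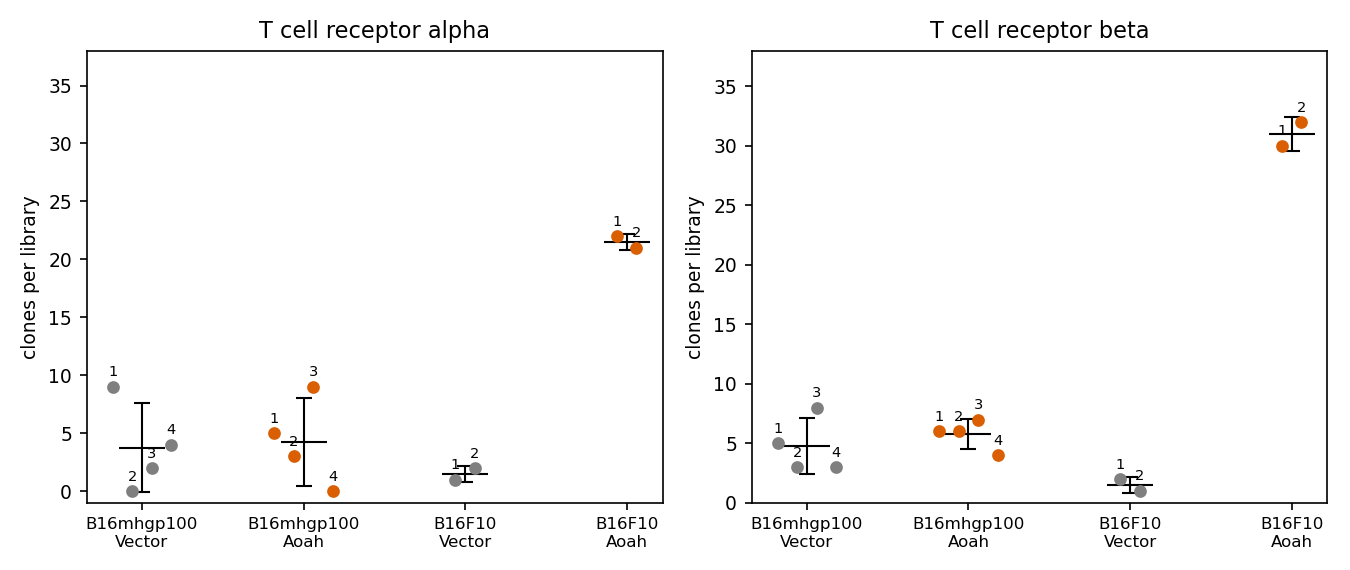
T cell receptor alpha and beta clones per library (vertical axes, linear), by group; points are libraries with their replicate numbers, and bars show the mean and SD. B16F10 Aoah tumours have 30 and 32 beta clones and B16F10 Vector tumours 2 and 1, read as totals over clonotypes and not as distinct receptors.

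The last comparison asks whether the same genes moved in both models. Across 13588 genes, which are not independent replicates, the log2 fold changes of the models correlated at r = 0.0871 and rho = 0.0958. Of 420 arrangements of the labels within the models, a share of 0.80 gave an r as far from 0 (exact permutation p = 0.80), and the highest r was 0.378. Without the library labelled Aoah 4, r was 0.207 (exact permutation p = 0.0381), and without Vector 2 of B16F10 it was 0.229 (exact permutation p = 0.0286). Without Vector 1 of B16F10 it was -0.0688.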

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

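The tests that weigh explanations in this part, and the list test of the difference between the models, were chosen only after the results were seen; the test of single genes for that difference was planned.

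For 5 genes the Aoah effect differed between the models by limma's interaction test, as B16mhgp100 minus B16F10. H2-DMb1 differed by -2.82, Psmb8 by -2.82 and Apol9a by -3.52, and the gene models Gm12238 and Gm56050 by -5.0 and 5.46. By limma's camera with the preset correlation 14 lists differed. The mean differences were -1.85 for T cells, -1.64 for CD8 and cytotoxic effectors, -1.65 for checkpoint genes and -1.87 for MHC class I, and these 4 also passed with an estimated correlation. They were -1.65 for MHC class II, -1.22 for CD4 and regulatory T cells, -1.70 for the interferon-gamma response, -1.10 for type I interferon-stimulated genes and -0.72 for melanocyte genes. They were 1.37 for fibroblasts, 0.51 for endothelium, 1.24 for skeletal muscle, 1.22 for red blood cells and 0.45 for eicosanoid genes. The latter 10 lists did not pass with an estimated correlation. With the preset correlation, the muscle, red blood cell and eicosanoid calls were lost without Aoah 4, at -0.17, 0.52 and 0.55, among other libraries. The endothelium call was lost without Vector 2 of B16F10, at 0.38, and the melanocyte call without Vector 1 of B16F10, at -0.66, or without Aoah 2 or Vector 2 of B16mhgp100, at -0.78 and -0.62. H2-DMb1 no longer passed without Vector 1, Vector 3 or Vector 4 of B16mhgp100, and Psmb8 and Apol9a without several single libraries.

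In 31 of 183 groups of 4 libraries, a single library lay apart from the rest. Its gap to the nearest exceeded the 95% critical share of the group's range in Dixon's test. Chance would give 9.15 for normal, independent values. These values were TPM, scores and repertoire measures, and most genes were picked by their p in the same libraries. Whether 31 exceeds chance was therefore not tested. The library labelled Aoah 4 of B16mhgp100 was the one that lay apart in 17 of the 31. It was high for the skin genes Krt14 (600.09 TPM, next 2.27) and Sfn (152.78 TPM, next 4.08), the muscle genes Mylpf (642.73 TPM) and Tnnt3 (865.36 TPM), the fat gene Cfd (245.24 TPM) and the haemoglobin genes Hba-a1 (969.48 TPM) and Hba-a2 (2257.47 TPM). It was also high for Pagr1a (56.34 TPM), Lat (6.8 TPM), Ikzf2 (4.86 TPM), Tnfrsf18 (7.66 TPM), Xcl1 (4.16 TPM) and the keratinocyte score (6.66). It was low for Dkc1 (37.68 TPM), Prf1 (1.35 TPM), Cxcl11 (9.93 TPM) and the cell cycle score (5.83).

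Among the other libraries of B16mhgp100, Vector 1 was high for Igkc (4.8 TPM), Sfn (29.3 TPM), Mylpf (111.02 TPM), Tnnt3 (90.49 TPM), Ptgis (2.9 TPM) and heavy chain clones (10 clones), and low for mt-Nd5 (698.42 TPM) and the mitochondrial score (10.2). Aoah 1 was high for Zbp1 (209.17 TPM), and Aoah 2 was high for Ankrd37 (29.1 TPM) and low for Lag3 (1.62 TPM). Vector 2 was low for H2-T23 (68.77 TPM), Vector 3 was low for the red blood cell score (3.94), and Vector 4 was high for Cd247 (6.58 TPM).

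The library labelled Aoah 4 differed from the others in skin, muscle and melanocyte genes and in transcript length. The length trend was removed from each library, and its median correlation with the others was then 0.855, below the lowest of 0.928 among the rest, which argues against length bias as the whole cause. Its keratinocyte score exceeded that of every other library by 4.63 and its muscle score by 2.17 log2 units, so skin and muscle in the tumour piece are a candidate source of those transcripts. Dilution by such tissue alone would lower genes made only by the tumour cells alike. The deviations of the melanocyte genes had an SD of 1.16 (at most 0.846 elsewhere), from 0.33 for Ednrb to -3.04 for Tyrp1. The length trend of this library was not removed from these values and could also spread them, so the SD cannot decide on dilution. A wrong label stays open, because Aoah at 3.91 TPM lies below the highest Vector library at 7.58 TPM and within tissue-mixed material a lower level cannot be told apart from a missing vector, and no biological explanation was tested.

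In B16F10 the T cell, CD8, checkpoint, CD4, interferon and MHC lists ranked higher in Aoah tumours with the preset correlation, 8 lists in all, and none of them passed with an estimated correlation (adjusted p from 0.354 to 0.384) or with fry. After removal of the length trend each of them passed with the preset correlation and kept at least 96.4% of its mean log2 fold change, which argues against length bias. The fibroblast list had a mean of -1.0 (SE 0.217 over its members, which are not independent replicates), so not all other cell types rose alike. A lower share of tumour cells through more immune cells alone would not raise fibroblast genes, so these values cannot decide whether that share fell. Melanocyte genes did not fall as a set, with a mean of 0.21, 11 above 0 and 4 below. Their level per tumour cell was not measured, so the share stays undecided. For 6 lists the lowest Aoah score exceeded the highest Vector score by more than the gap between the Vector libraries, which argues against a single low Vector library as their source. For the other 2, CD4 and regulatory T cells and type I interferon-stimulated genes, the gap between the Vector libraries was larger. How much of their rise came from a low Vector library cannot be told apart from an Aoah effect. Their lowest Aoah score still lay above the highest Vector score, by 0.54 and 0.63, a distance that rests on 1 Vector library. An Aoah effect in the 6 lists separated by more than that gap remains a hypothesis that rests on 4 libraries.

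For the counts in B16mhgp100, the 8 libraries can be split into 4 and 4 in 35 ways. The real count of genes is 0, so 35 of 35 splits reach it by necessity and nothing follows for that count, and the highest other split gave 2. For lists, 9 of 35 splits gave at least the real 14, and the highest other split gave 16. Chance is therefore not excluded for the count of lists.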

How the results depend on the processing

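The length correction, the crossed pairing, the joint fit with an estimated correlation, the fit without Aoah 4 with one, and all list tests of the difference were chosen after seeing the data; the others were planned. The count model was not run, since no counts per library were used. Unless stated, the cause was not tested. In B16mhgp100, 0 genes passed in limma under most settings, 1 with log2(TPM + 0.1) and 5 with array weights; leaving out a library gave 0 to 2 (1 without Aoah 1 or Vector 4, 2 without Aoah 4). Its 14 lists became 0 with an estimated correlation, with fry, in the fit of all 12 libraries with an estimated correlation, and without Aoah 4 with one, and 9 to 17 without single libraries (9 without Aoah 2). The red blood cell list ran from -0.23, without Aoah 4 by either correlation, to 0.81.

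In B16F10 the 50 genes became 32 with log2(TPM + 0.1), 0 with no filter, 29 with a mean of at least 5 TPM, 127 with median-of-ratios scaling, 81 rescaled, 115 with array weights and 189 after length correction. Leaving out any library gave 0, a fit with a lone sample assumed to vary like the other group. Its 15 lists became 0 with an estimated correlation and with fry, and 5 in the fit of all 12 with an estimated correlation. The mitochondrial list ran from -0.95 without Vector 1 to 0.10 without Vector 2. The Aoah difference was 4.29 with log2(TPM + 0.1) and 3.25 to 3.76 without single libraries. As clonotypes per clone, the alpha ratios of 0.864 and 0.810 and beta ratios of 0.667 and 0.656 in Aoah tumours lay below the 1 of both Vector libraries, which hold 1 or 2 clones of each of these chains, and the light chain ratios overlapped.

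For the difference, the 5 genes became 46 with no filter, 10 with median-of-ratios scaling, 8 rescaled, 31 with array weights, 18 after length correction and 2 to 45 without single libraries (45 without Aoah 4, 23 and 11 without B16F10 Aoah 2 and 1, 22 and 16 without B16F10 Vector 2 and 1, 3 without Aoah 2 or Vector 4, and 2 without Vector 1 or Vector 3). Its 14 lists became 4 with an estimated correlation and 6 with fry, and its skeletal muscle list ran from -0.29 without B16F10 Vector 2 to 2.77 without B16F10 Vector 1. The correlation of effects ran from -0.0688 to 0.229 without single libraries.

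Deviations from the group means of libraries with equal replicate numbers correlated at -0.254, -0.289, 0.0168 and -0.057 in B16mhgp100 and -0.108 in B16F10. These values gave no sign of pairs but cannot exclude them. With 2 libraries per group, both numbers of B16F10 give the same value by necessity. With the number as a replicate block, 765 genes passed in B16F10 and 2 in the difference, and the crossed pairing gave 910. With the block, 15, 16 and 15 lists passed in B16mhgp100, B16F10 and the difference.

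Of the values of single named genes under the alternatives, 0 changed direction after a call; in B16F10, 1051 stayed on their side of the threshold, 127 lost it, 184 gained it and 145 moved by more than 1 SD without passing. In B16mhgp100 the numbers were 994, 0, 4 and 13, and for the difference 1011, 23, 34 and 69. No gene was called in B16mhgp100, so none could lose a call there. Turns in direction of uncalled genes are not counted as such. Depth per library is unknown, so its limits were not measured.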

Other observations

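The tests of genes in this part were planned over all genes, but these genes were picked for mention after their values were seen, and no explanation was tested.

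Some genes past the threshold in B16F10 stand in none of the lists. Their calls rest on 4 libraries, and fits with 1 of the 4 left out cannot judge them. Ctsw, a cathepsin of cytotoxic lymphocytes, rose by 2.84 on the log2 scale (limma adjusted p = 0.0433), Ptprcap, which binds the lymphocyte phosphatase CD45, by 2.63 (adjusted p = 0.043), and Ms4a4b by 2.44 (adjusted p = 0.0433). H2-T22, a non-classical class I gene, rose by 2.49 (adjusted p = 0.0321), Ube2l6, an enzyme of ISG15 conjugation, by 2.03 (adjusted p = 0.0343) and the complement gene C4b by 2.09 (adjusted p = 0.0321). Axl, a receptor tyrosine kinase gene, stood at 118.08 and 136.99 TPM in Aoah and 17.62 and 18.56 TPM in Vector tumours of B16F10, and at 121.89, 82.43, 70.65 and 23.99 TPM in Aoah and between 62.41 and 72.34 TPM in Vector tumours of B16mhgp100. Smpd1 and Hpse, which encode acid sphingomyelinase and heparanase, rose by 1.82 and 1.85 (adjusted p = 0.0286 and 0.0321).

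Retnla values were 48.95, 203.82, 5.32 and 992.11 TPM in the libraries labelled Aoah 1 to Aoah 4 of B16mhgp100 and between 4.85 and 9.87 TPM in the Vector tumours. In B16F10 they were 18.87 and 15.48 TPM in Aoah and 570.61 and 339.8 TPM in Vector tumours. The difference of the effects was 8.28 (SE 2.03) and did not pass (limma adjusted p = 0.399). In B16F10, Ear2, an eosinophil-associated ribonuclease, stood at 4.82 and 3.77 TPM in Aoah and 35.32 and 18.4 TPM in Vector tumours. Ccl24, an eotaxin gene, stood at 1.84 and 1.35 against 42.62 and 10.18 TPM, and Rnase2a at 0.38 and 0 against 65.07 and 14.18 TPM. None of these 3 passed in B16F10 (adjusted p = 0.0739, 0.115 and 0.0696).

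The B16F10 Vector tumours had the lowest group means for several presentation genes. Psmb8 stood at 89.1 ± 42.6 TPM there (SD, n = 2), against 415 ± 67.8 TPM in B16mhgp100 Vector tumours (SD, n = 4) and 532 ± 63.6 TPM in B16mhgp100 Aoah tumours (SD, n = 4). H2-K1 stood at 582 ± 180 TPM (SD, n = 2) against 1844 ± 298 TPM in B16mhgp100 Vector tumours (SD, n = 4). Whether this level belongs to the cell line, the antibodies or the day was not separable by design.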
